A study of Homo sapiens with 6 samples.

How the data were processed

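The data are RNA-seq gene counts for 6 libraries of MDA-MB-231 cells, 3 of control cells and 3 of cells labelled as knockouts of ETV1, ETV4 and ETV5. Per the labels' protocols, cells were grown in droplets of collagen I, released with collagenase, and their RNA was column-purified and made into stranded libraries of poly(A)-selected mRNA. The deposited table holds raw counts of reads per gene for 61228 gene names; the values are whole numbers that sum to a different total in each library, and per the submitters' processing notes the tools were FastQC 0.11.9, STAR 2.7.9a, featureCounts and R 4.1.1 with genome build hg38. The version and strand setting of featureCounts, the gene annotation and the treatment of reads that map to several places are not given in the sources used here. Reads from overlapping or antisense genes therefore cannot be told apart with certainty, and genes with near-identical copies (cystatins, AKR1C and IFIT genes, histones) are uncertain. The count columns were assigned to samples by the names in the table's header. In the table, 32466 genes had no count in any library.

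Groups were taken from the treatment label and replicate numbers from the sample titles. The titles name ETV4 alone, while the treatment label names all 3 targeted genes; the latter was used. Choices of test, filter, gene lists, named genes and the alternatives were fixed before the data were examined, except where stated otherwise. Genes were kept by edgeR's filterByExpr, which left 14704, and scaled with TMM factors. The comparison used edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) on the deposited counts with group as the single term, Benjamini-Hochberg adjustment and a threshold of 0.05, with no limit on fold change. Fold changes, SE and CPM (counts scaled to library size with TMM factors) were computed here. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

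The 34 gene lists were written from general knowledge. They were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes and, beside it, with a correlation estimated for each list, and with fry, which tests whether a list's genes move on balance in a single direction without comparing them to other genes. Adjustment ran over the 33 lists with at least 5 measured members; the fibroblast list had 4. Members were counted from the gene test over all genes, and again with p-values adjusted over the list alone. The camera test called 15 lists, 7 higher and 8 lower; fry called 19, 6 higher and 13 lower.

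The named genes follow a rule. They are ETV1, ETV4 and ETV5; the 10 genes with the largest increase and the 10 with the largest decrease among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, passing over genes without an established symbol; and up to 3 members per direction with the smallest adjusted p in each list that was called or had 3 or more members past the test, or 2 members in other lists. Positions and Ensembl identifiers are from GENCODE release 29 on GRCh38, in which 97.7% of the tested genes were found by name; it may differ from the annotation used for counting.

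Both groups carry the replicate numbers 1, 2 and 3 in the labels, which say nothing of a shared day or batch. The deviations of each library from its group mean, over 10032 genes with a mean log2 CPM above 3, were correlated between groups. The same-numbered pairs gave correlations of 0.55, 0.45 and 0.83 across genes (genes are not independent replicates), each above 0.1, and the numbers were therefore treated as pairing the samples; this pairing comes from the data, not from the design. Control replicate 1 correlated best with KO replicate 2 (0.59) and control replicate 2 with KO replicate 1 (0.58), so the shared structure is mainly that of replicate 3. Values from the fit with replicate as a block are given beside results where they change a call or move a count by more than 1.5 times.

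The procedure was tested on simulated data before use. Counts were drawn independently for each gene, with 14478 genes in the fit and 200 genes changed. They used the library sizes of the real libraries, and the means and dispersions of the replicate-block fit without its group effect. The group comparison recovered 8% of 50 genes changed 1.25-fold, 38% at 1.5-fold, 82% at 2-fold and 92% at 4-fold, and edgeR called 0 of 14249 unchanged genes. With the replicate block, recovery was 74%, 76%, 94% and 98%, and 28 unchanged genes were called. Camera called the list that had been moved and 0 of 33 lists that had not. As the simulated genes were not correlated, this does not show how often camera calls unmoved lists of correlated genes. The biological coefficient of variation was 10.5% in the group fit and 4.13% with the block.

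Library totals ran from 18042601 to 23232770 counts, and 3 counts, the limit that a count of 0 allows, are worth between 0.129 and 0.166 CPM; these limits cover counting error only. Alternatives fixed in advance were DESeq2, limma-voom, other scalings (DESeq2 size factors, library totals), no filter or a stricter filter (5 CPM in 3 libraries), robust estimation off, the replicate block with and without the 20 most abundant genes, leaving out those 20 genes, glmTreat against a log2 fold change of 1, an estimated correlation, fry, and leaving out each library in turn. Added after the data were seen were a batch term of 2 levels (replicate 3 against replicates 1 and 2), leaving out both replicate-3 libraries, and the block with an estimated correlation. Reads were not analysed here.

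Results for 3 single genes are not reported here; the counts, medians and tests of gene lists include all measured members.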

Results

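Polyadenylated RNA was sequenced from MDA-MB-231 cells, a human breast cancer line of the basal, triple-negative type, that had been grown in 3D gels of collagen I, the main fibrillar collagen of connective tissue. The series compared 2 groups of 3 libraries each. Control cells received the Cas9 nuclease with control guide RNAs by nucleofection, an electrical method of delivery into cells. The treatment label of the knockout cells (KO) gives knockout of ETV1, ETV4 and ETV5, while their sample titles name ETV4 alone. These genes encode a family of related ETS transcription factors that act downstream of receptor and ERK signalling. Counts assigned to genes summed to 21399230, 18806653 and 23232770 in control replicates 1, 2 and 3, and to 18740354, 19250921 and 18042601 in KO replicates 1, 2 and 3. Nothing in the labels says whether replicates of a group are separate cultures, so the p-values measure only the spread between these samples, which may be technical. The names of the 3 KO libraries share the tag c39, which the labels do not explain. It is not stated whether these libraries come from a single clone, in which case a difference between the groups may be that clone's, nor which of the collagen concentrations named in the protocol was used for which sample. CPM values are means ± SD over the n = 3 libraries of a group, and log2 fold changes are KO over control with their standard error (SE).

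The libraries separated by group along the first principal component, which held 49.3% of the variance. The next component, with 39.4%, set replicate 3 of both groups apart from replicates 1 and 2. Between replicate pairs of a group, the lowest chi-square per degree of freedom was 4.19, for control replicates 1 and 2, so no pair of libraries matched within sampling noise. Mitochondrially encoded transcripts took 3.15%, 4.26% and 3.25% of the control counts and 3.82%, 2.65% and 2.95% of the KO counts.

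**Figure D1:**
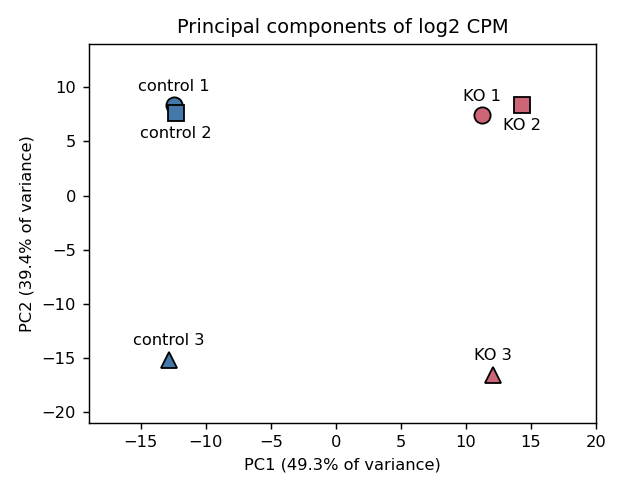
Principal components of log2 CPM for the 6 libraries, with PC1 on the x axis (49.3% of variance) and PC2 on the y axis (39.4%); blue marks control, red marks ETV1/4/5 KO, and circle, square and triangle mark replicates 1, 2 and 3. The groups separate along PC1, and both triangles separate from the other libraries along PC2.

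Of the targeted genes, ETV1 and ETV4 transcripts were lower in the KO libraries and ETV5 transcripts were not. ETV1 (ENSG00000006468, GRCh38 chromosome 7, 13891228 to 13991425, minus strand) fell from 223 ± 13.5 to 142 ± 11.1 CPM, a log2 fold change of -0.65 (SE 0.08, edgeR adjusted p = 0.00125). Its values were 218, 213 and 238 CPM in the controls and 135, 137 and 155 CPM in the KO libraries. ETV4 (ENSG00000175832, chromosome 17, 43527844 to 43579620, minus strand) fell from 93.9 ± 2.11 to 63.7 ± 2.03 CPM, a log2 fold change of -0.56 (SE 0.06, edgeR adjusted p = 6.12e-04). ETV5 (ENSG00000244405, chromosome 3, 186046308 to 186110318, minus strand) measured 112 ± 4.77 CPM in control and 113 ± 1.23 CPM in KO, with a log2 fold change of 0.01 (SE 0.06, edgeR adjusted p = 0.93). Small Cas9 insertions or deletions need not lower the count of a gene's mRNA, so counts over whole genes do not show how completely each gene was disrupted.

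**Figure D2:**
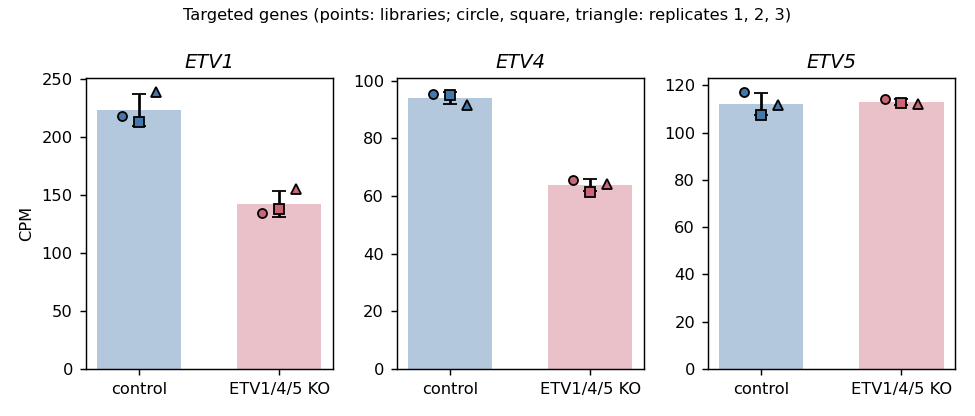
CPM of ETV1, ETV4 and ETV5 in control and ETV1/4/5 KO libraries; bars are means of 3 libraries, error bars are SD, and points are single libraries. The KO values of ETV1 and ETV4 lie below every control value, while the ETV5 means are 112 and 113 CPM.

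Among genes with an established symbol and a mean of at least 5 CPM, the 10 largest decreases included secreted cystatins and genes of the hypoxia response. CST1, a salivary-type cystatin that inhibits cysteine proteases, fell from 73.7 ± 5.97 to 6.06 ± 0.24 CPM (12.1-fold lower, log2 fold change -3.60, SE 0.09, edgeR adjusted p = 2.37e-07), and its neighbour CST4 was 9.60-fold lower (log2 fold change -3.26, SE 0.11). CA9, the cell-surface carbonic anhydrase IX, fell from 41.2 ± 3.27 to 3.40 ± 0.23 CPM (12.1-fold lower, SE of the log2 fold change 0.11, edgeR adjusted p = 5.10e-07). NDRG1, an abundant stress-responsive gene, fell from 577 ± 23.2 to 95.6 ± 3.64 CPM, a 6.03-fold decrease. The liprin gene PPFIA4 (9.44-fold), INHBB, an activin subunit (5.22-fold), the dynein heavy chain gene DNAH11 (5.06-fold), the phosphodiesterase PDE2A (4.40-fold), the aldolase ALDOC (3.85-fold) and SPAG4 (3.64-fold) were also lower.

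Among genes that rose, OASL, an interferon-induced gene of the oligoadenylate synthetase family, went from 6.76 ± 0.42 to 25.2 ± 2.35 CPM (3.72-fold, log2 fold change 1.90, SE 0.11, edgeR adjusted p = 3.93e-05). CYP1B1, a xenobiotic-metabolising cytochrome P450, went from 10.8 ± 1.31 to 39.1 ± 1.12 CPM (3.60-fold, SE of the log2 fold change 0.10, edgeR adjusted p = 2.49e-05). The gel-forming mucin MUC5AC rose 2.98-fold, CRISPLD2 2.82-fold, the aquaporin AQP3 2.80-fold, the cytokine IL24 2.33-fold, ID3, an inhibitor of basic helix-loop-helix factors, 2.27-fold, IFIT1 2.16-fold and AKR1C1 2.13-fold. The most abundant of the genes with large increases was THBS1, which encodes the matrix glycoprotein thrombospondin-1 and went from 402 ± 8.75 to 853 ± 23.6 CPM (2.12-fold, SE of the log2 fold change 0.06). CST1 with CST4, and AKR1C1 with other AKR1C genes, have near-identical copies, so how their reads were divided between copies is uncertain.

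Over all genes, 1427 of 14704 tested passed edgeR's quasi-likelihood test, 483 higher and 944 lower in KO (33.8% and 66.2%); 49 of the higher and 175 of the lower genes changed at least 2-fold. With the replicate number as a block, 4983 genes passed, 2522 higher and 2461 lower (50.6% and 49.4%). Among them were 1426 of the 1427, each in the same direction. In the simulation the block called more unchanged genes than its threshold allows, so its counts here and below may be too high. The control and KO values did not overlap for 31.7% of tested genes, against 10% by chance for 3 against 3. The number of genes depended on single libraries: 591 passed without control replicate 1, 572 without control replicate 2, 686 without KO replicate 1 and 662 without KO replicate 2. Without both replicate-3 libraries, a setting chosen after the data were seen, 3754 passed, 1731 higher and 2023 lower.

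**Figure D3:**
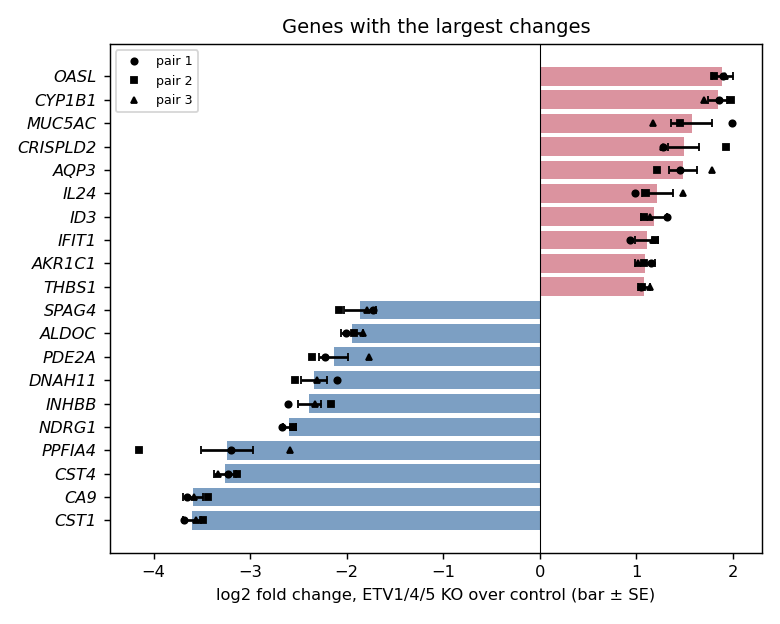
Log2 fold changes (x axis, ETV1/4/5 KO over control) of the 10 genes with the largest increase and the 10 with the largest decrease among genes past the test with a mean of at least 5 CPM; bars are fitted values with SE, and points are the differences between same-numbered libraries. The genes were also chosen for no overlap between the groups, so the differences of the 3 pairs lie on the same side of 0 by that choice.

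Genes of the hypoxia response, the set induced through hypoxia-inducible factors when oxygen is low, were lower in KO for the larger part. Of 30 measured members, 21 fell, 1 rose and 8 did not pass; 24 fell and 1 rose when adjusted over the list alone, and the median log2 fold change was -0.63. Besides CA9, NDRG1 and PPFIA4, the mitophagy receptor BNIP3 fell from 460 ± 14.3 to 167 ± 8.92 CPM (log2 fold change -1.46, SE 0.07, edgeR adjusted p = 1.08e-05). ADM, which encodes the vasodilator peptide adrenomedullin, was the member that rose, from 55.9 ± 1.02 to 73.3 ± 2.76 CPM (log2 fold change 0.39, SE 0.06, edgeR adjusted p = 0.00463). The list passed camera, a competitive gene set test, at adjusted p = 1.20e-16, and at adjusted p = 0.0111 with an estimated correlation. It did not pass camera with the replicate block and an estimated correlation (adjusted p = 0.225). That setting leaves few residual degrees of freedom with 6 libraries and so has little power. With the block, fry gave adjusted p = 7.23e-04 for the list. Enzymes of glycolysis shared the direction: 12 of 17 fell and 5 did not pass, 14 fell when adjusted over the list alone, and the median was -0.36 (camera adjusted p = 1.41e-08; adjusted p = 0.147 with an estimated correlation). PGK1, phosphoglycerate kinase, fell from 1414 ± 98.6 to 745 ± 60.5 CPM (log2 fold change -0.92, SE 0.08), and the phosphofructokinase PFKL had a log2 fold change of -0.64 (SE 0.06). Without control replicate 1, KO replicate 1 or KO replicate 2, 7 glycolysis genes fell.

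Genes of cholesterol synthesis and uptake were lower in KO. Of 24 measured members, 19 fell and 5 did not pass; 20 fell when adjusted over the list alone, and the median log2 fold change was -0.65. The sterol methyl oxidase MSMO1 went from 116 ± 6.70 to 53.7 ± 4.30 CPM (log2 fold change -1.11, SE 0.08), and SQLE, squalene epoxidase, from 78.7 ± 0.92 to 45.2 ± 1.05 CPM (log2 fold change -0.80, SE 0.06). The list passed camera at adjusted p = 1.20e-16 and at adjusted p = 0.0111 with an estimated correlation. Hypoxia and cholesterol were the only lists of the 33 tested that passed camera with an estimated correlation in the group comparison. With the replicate block and an estimated correlation, a setting of little power, the lowest camera adjusted p of any list was 0.225.

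Genes that build and cross-link extracellular matrix were lower in part. Among 38 measured collagens, matrix proteins and matrix-modifying enzymes, 19 fell, 2 rose and 17 did not pass; 23 fell and 3 rose when adjusted over the list alone, with a median log2 fold change of -0.33. The prolyl hydroxylase P4HA1 (log2 fold change -1.10, SE 0.07), the transmembrane collagen COL13A1 (-1.19, SE 0.07) and the lysyl oxidase LOX (-1.22, SE 0.08) fell, while THBS1 and the fibrillin FBN2 (1.60, SE 0.25, at 0.87 ± 0.21 and 2.67 ± 0.23 CPM) rose. P4HA1 and LOX also belong to the hypoxia list. The camera test gave adjusted p = 1.98e-06, and adjusted p = 0.264 with an estimated correlation. Without control replicate 1 or control replicate 2, 12 of the matrix genes fell; with the replicate block 4 rose.

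Among integrins and focal adhesion genes, 7 of 32 fell, 1 rose and 24 did not pass (8 lower and 3 higher when adjusted over the list alone). ITGB4, the beta subunit of the laminin-binding integrin of hemidesmosomes, fell from 495 ± 54.9 to 152 ± 17.2 CPM (log2 fold change -1.70, SE 0.11, edgeR adjusted p = 6.08e-05), and ITGB3 and ITGB2 had log2 fold changes of -1.43 (SE 0.15) and -0.83 (SE 0.09). ITGB8 was the member that rose (log2 fold change 0.56, SE 0.11); its edgeR adjusted p went from 0.0137 to as much as 0.0639 with 1 library left out. With the replicate block 16 of these genes were lower and 7 higher. The list passed camera at adjusted p = 0.0145, with adjusted p = 0.572 with an estimated correlation, and did not pass without KO replicate 3 (adjusted p = 0.209), where 4 members rose. Without control replicate 3, 2 rose, and without any other single library ITGB8 no longer passed.

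Proteases of the cell surface moved in both directions. Of 26 measured matrix metalloproteinases and other pericellular proteases, 8 fell, 4 rose and 14 did not pass (9 lower and 5 higher when adjusted over the list alone; camera adjusted p = 0.383). PLAT, tissue plasminogen activator, fell from 378 ± 11.1 to 143 ± 1.24 CPM (log2 fold change -1.40, SE 0.06, edgeR adjusted p = 6.04e-06), and ADAM8 and the urokinase gene PLAU had log2 fold changes of -0.65 (SE 0.07) and -0.51 (SE 0.07). ADAMTS9 (0.94, SE 0.09), ADAMTS1 (0.52, SE 0.08) and MMP16 (0.87, SE 0.13) rose. Of 17 measured protease inhibitors, 3 fell and 2 rose, the same counts when adjusted over the list alone (camera adjusted p = 0.669; median log2 fold change -0.07, mean 0.07). The plasminogen activator inhibitor SERPINB2 rose from 0.72 ± 0.08 to 5.14 ± 0.90 CPM, TFPI2 rose (log2 fold change 0.81, SE 0.08), and TFPI (-0.62, SE 0.06) and CST3 (-0.69, SE 0.07) fell. Without control replicate 1 or 2 or KO replicate 1 or 2, 3 of the proteases fell; with the replicate block 7 rose and 11 fell, and 4 inhibitors rose.

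Part of the interferon response was higher in KO. Of 36 measured members, 14 rose, 1 fell and 21 did not pass, with the same counts when adjusted over the list alone, and the median log2 fold change was 0.13. IFI44 went from 16.7 ± 0.32 to 30.4 ± 0.49 CPM (log2 fold change 0.86, SE 0.07, edgeR adjusted p = 2.43e-04) and IFIT2 from 16.6 ± 1.49 to 31.1 ± 1.34 CPM (log2 fold change 0.91, SE 0.09), beside OASL and IFIT1. ISG20, an interferon-induced exonuclease, was the member that fell (2.01-fold lower, SE of the log2 fold change 0.19, edgeR adjusted p = 0.0127); without control replicate 1 or KO replicate 2 it did not pass. The list passed camera at adjusted p = 7.50e-04, with adjusted p = 0.139 with an estimated correlation, and 9 members rose without control replicate 1, control replicate 2 or KO replicate 1, and 8 without KO replicate 2; with the replicate block 2 fell. IFIT genes are similar in sequence, so the division of reads among them is uncertain. In the list of NF-kB targets and inflammatory cytokines, 4 of 29 rose and 1 fell (6 and 5 when adjusted over the list alone; camera adjusted p = 0.401), among them PTGS2, the inducible cyclooxygenase (log2 fold change 0.76, SE 0.09), and IL11 (0.56, SE 0.08). The median of that list was -0.04 and its mean 0.08. The adhesion receptor ICAM1 was the member that fell (-0.69, SE 0.14) and did not pass without control replicate 1 or 2. Without control replicate 3 or KO replicate 3, 2 and 3 members fell; with the replicate block 7 rose and 6 fell.

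Some cell cycle genes were slightly higher in KO. In the list of DNA replication and S phase genes, 10 of 39 rose and 29 did not pass; 20 rose when adjusted over the list alone, and 36 with the replicate block. The median log2 fold change was 0.22 (camera adjusted p = 2.07e-11; adjusted p = 0.147 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, went from 269 ± 6.83 to 399 ± 10.5 CPM (log2 fold change 0.57, SE 0.06, edgeR adjusted p = 6.12e-04), and CCNE2, cyclin E2, and CLSPN, a replication checkpoint adaptor, had log2 fold changes of 0.53 (SE 0.07) and 0.46 (SE 0.06). Of 38 mitosis and G2/M genes, 4 rose, 10 when adjusted over the list alone and 27 with the replicate block, where 1 fell; the median was 0.15 (camera adjusted p = 5.61e-07; adjusted p = 0.279 with an estimated correlation). KIF4A, a chromosome-associated kinesin, rose (0.32, SE 0.06). It did not pass in 3 of the 6 fits with 1 library left out (edgeR adjusted p of up to 0.0709). Of 12 histone genes of the replication-dependent class 6 were higher, 7 when adjusted over the list alone, with a median of 0.69 (camera adjusted p = 9.48e-07; adjusted p = 0.0583 with an estimated correlation). The linker histone gene H1-2 rose from 39.6 ± 3.55 to 75.2 ± 3.52 CPM (log2 fold change 0.93, SE 0.08). Most transcripts of this class carry no poly(A) tail and many have near-identical copies, so counts from a poly(A) library cover them in part. Without KO replicate 3, 4 histone genes rose, and at most 2 without any other library. Without control replicate 1 or 2, 3 S phase genes rose, 4 without KO replicate 1, 5 without KO replicate 2 and 19 without KO replicate 3; 11 mitosis genes rose without KO replicate 3 and at most 2 without any other library.

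**Figure D4:**
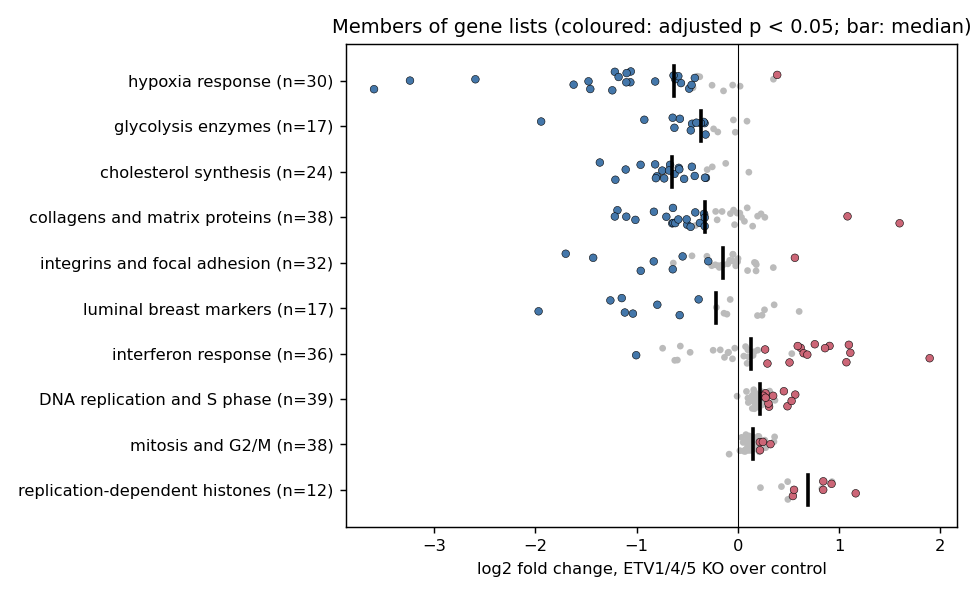
Log2 fold changes (x axis, ETV1/4/5 KO over control) of the measured members of 10 gene lists (y axis, n is the number measured); each point is a gene, colour marks an edgeR adjusted p under 0.05, and the black bar is the median. Medians run from -0.65 for cholesterol synthesis to 0.69 for replication-dependent histones.

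Genes tied to the targeted factors and to their upstream signals changed in part. In the list of 19 measured ETS factors, ETV1, ETV4 and ELK3 fell, also when adjusted over the list alone. The remaining 16 did not pass, and the list had camera adjusted p = 0.242. ELK3 had a log2 fold change of -0.26 (SE 0.06, edgeR adjusted p = 0.0381). It did not pass in 5 of the 6 fits with 1 library left out (edgeR adjusted p of up to 0.167). The replicate block gave 5 lower and 3 higher ETS genes, and without KO replicate 3, 1 was higher. Of 29 genes that report or restrain ERK signalling, 7 fell and 5 rose (10 and 6 when adjusted over the list alone; camera adjusted p = 0.463). The ERK phosphatase DUSP6 fell from 488 ± 0.62 to 331 ± 8.54 CPM (log2 fold change -0.56, SE 0.06, edgeR adjusted p = 5.77e-04) and the feedback inhibitor SPRY1 from 66.0 ± 2.51 to 45.4 ± 0.73 CPM (-0.54, SE 0.06). IL11 rose. With 1 library left out, between 4 and 9 of the ERK genes fell and between 1 and 5 rose, with 1 higher without control replicate 1 and 4 lower without control replicate 2, KO replicate 1 or KO replicate 2; with the replicate block 12 fell and 9 rose. In the FGF list, 0 of 11 genes passed edgeR or limma-voom, 0 of 20 passed DESeq2, and 2 had an unadjusted p under 0.05 in edgeR; 1 fell without KO replicate 3, and with the replicate block 2 were higher and 1 lower (camera adjusted p = 0.816). FGFR3 had a log2 fold change of 0.77 (SE 0.23, edgeR adjusted p = 0.071; 0.0211 with the block) and FGFBP3 of -0.37 (SE 0.12, 0.0847 and 0.0107).

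Markers of breast epithelium moved as follows. Of 17 luminal markers 8 were lower and 9 did not pass (9 lower and 3 higher when adjusted over the list alone; median -0.21; camera adjusted p = 0.00343; adjusted p = 0.264 with an estimated correlation). CA12, a carbonic anhydrase, was 2.21-fold lower (log2 fold change -1.15, SE 0.07), KRT19, keratin 19, from 704 ± 30.2 to 406 ± 13.4 CPM (-0.80, SE 0.06), and the protein disulfide isomerase AGR2 had a log2 fold change of -1.04 (SE 0.10). Without both replicate-3 libraries the luminal list had camera adjusted p = 0.054, without control replicate 1, 5 members fell, and without KO replicate 3, 2 rose. Of 13 basal markers 5 fell, ITGB4 among them, and 1 rose (7 and 3 when adjusted over the list alone; camera adjusted p = 0.0524; 0.0305 without control replicate 1, 0.0387 without KO replicate 1 and 0.0262 without KO replicate 2). Of 22 epithelial markers 4 fell and 1 rose (4 and 2 when adjusted over the list alone; camera adjusted p = 0.398), among them the claudin CLDN4 (-0.90, SE 0.08). Of 26 mesenchymal markers 6 fell and 3 rose (10 and 4 when adjusted over the list alone; camera adjusted p = 0.178), among them S100A4 (-0.55, SE 0.07) and LOXL2 (-0.51, SE 0.07). With 1 library left out, between 2 and 5 basal markers and between 2 and 7 mesenchymal markers fell, the lowest counts of both without control replicate 1, control replicate 2 or KO replicate 2. In these fits between 0 and 2 basal, between 0 and 3 mesenchymal and between 1 and 3 epithelial markers rose, and between 2 and 4 epithelial markers fell. With the replicate block, 3 luminal markers rose, 3 basal markers rose and 7 fell, 3 epithelial markers rose, and 5 mesenchymal markers rose and 12 fell.

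Of the markers of other cell types measured in this single line, some of endothelium and leukocytes were lower in KO. Of 7 measured endothelial markers, 3 fell, 3 also when adjusted over the list alone (camera adjusted p = 0.00347; adjusted p = 0.279 with an estimated correlation). ROBO4, a guidance receptor, was 2.60-fold lower, at 20.3 ± 1.96 CPM in KO (log2 fold change -1.38, SE 0.09). Without control replicate 1, control replicate 2 or KO replicate 1 it was the sole member of that list that fell. Of 6 measured leukocyte markers, lysozyme (LYZ, 6.03 ± 0.25 to 1.55 ± 0.27 CPM) and CD74 (115 ± 5.58 to 89.4 ± 3.19 CPM) fell, 2 also when adjusted over the list alone (camera adjusted p = 0.029; adjusted p = 0.279 with an estimated correlation; 0.0709 with the replicate block; 0.162 without control replicate 2). Of the 4 measured fibroblast markers 0 passed edgeR or limma-voom and 0 of 14 passed DESeq2; 1 had an unadjusted p under 0.05 and 1 fell when adjusted over the list alone and with the replicate block.

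Among the remaining signalling lists, Wnt targets passed camera (adjusted p = 0.0323; 0.264 with an estimated correlation; 0.0709 with the replicate block), with 2 of 15 members higher, 4 when adjusted over the list alone and 6 with the block, where 1 fell. Without KO replicate 3, 5 rose and 1 fell. The growth factor BMP4 went from 136 ± 1.36 to 211 ± 2.69 CPM (log2 fold change 0.63, SE 0.05) and the Wnt antagonist DKK1 from 349 ± 17.2 to 548 ± 29.2 CPM (0.65, SE 0.07). The Wnt list did not pass without control replicate 3 (adjusted p = 0.0639) or KO replicate 3 (0.0621). Of 27 TGF-beta targets 6 rose and 5 fell (7 and 7 when adjusted over the list alone; camera adjusted p = 0.559), among them ID3, the transcriptional repressor BHLHE40 (-0.62, SE 0.08) and LTBP2 (-0.67, SE 0.10). Of 27 YAP/TAZ targets 3 rose and 4 fell, the same when adjusted over the list alone (camera adjusted p = 0.865); tissue factor, F3, went from 191 ± 5.74 to 348 ± 18.3 CPM (0.87, SE 0.06) and IGFBP3 fell (-0.63, SE 0.06). Of 31 angiogenic and guidance factors 5 rose and 6 fell (5 and 7 when adjusted over the list alone; camera adjusted p = 0.149, and 0.0335 without control replicate 3), among them EPHB2 (0.50, SE 0.08), SEMA4B (-0.93, SE 0.09) and SEMA3B (-0.81, SE 0.09). With 1 library left out, between 2 and 6 TGF-beta targets rose and between 2 and 5 fell, between 1 and 4 YAP/TAZ targets rose and between 1 and 3 fell, and between 2 and 6 angiogenic factors rose, each lowest count of risers being found without control replicate 2, KO replicate 1 or KO replicate 2. With the replicate block, 10 TGF-beta targets fell, 8 YAP/TAZ targets rose and 6 fell, and 10 angiogenic factors fell.

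The lists for stress, motility, Notch signalling and housekeeping functions gave the following counts. Of 24 p53 targets 2 rose, PLK2 (0.56, SE 0.06) and CDKN1A (0.33, SE 0.07). When adjusted over the list alone 4 were higher and 2 lower (camera adjusted p = 0.397). CDKN1A did not pass in 5 of the 6 fits with 1 library left out (edgeR adjusted p of up to 0.101). Of 33 unfolded protein and ATF4 response genes 2 rose and 5 fell (5 and 7 when adjusted over the list alone; camera adjusted p = 0.982; median 0.0019, mean -0.01), with VLDLR lower (-0.58, SE 0.07). Of 32 actomyosin and motility genes 1 rose, RHOB (0.41, SE 0.06), and 6 fell (1 and 7 when adjusted over the list alone; camera adjusted p = 0.149), with the actin bundler FSCN1 lower (-0.44, SE 0.08). Of 13 Notch genes HES1 and HES4 rose, with 2 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.52, median -0.18). With 1 library left out, HES1 did not pass in 5 of the 6 fits and HES4 in 6 of 6 (edgeR adjusted p of up to 0.143 and 0.154). The replicate block gave 3 higher and 4 lower Notch genes. In the list of genes induced by tissue dissociation and heat, 5 of 29 rose and 4 fell (8 and 5 when adjusted over the list alone; camera adjusted p = 0.337); JUN fell (-0.54, SE 0.10) and did not pass without KO replicate 1 or KO replicate 2 (edgeR adjusted p of up to 0.0603). Cytosolic ribosomal protein genes, with 0 of 39 past edgeR, DESeq2 or limma-voom and 4 at an unadjusted p under 0.05, had a median of 0.08 (camera adjusted p = 0.0145; adjusted p = 0.459 with an estimated correlation; 0.109 without KO replicate 2 and 0.0682 without control replicate 3), and with the replicate block 19 were higher and 1 lower. Nuclear-encoded respiratory chain genes, with 0 of 37 past edgeR and limma-voom, 1 past DESeq2 and 2 at an unadjusted p under 0.05, had a median of 0.09 (camera adjusted p = 0.029; adjusted p = 0.527 with an estimated correlation; 0.141 without KO replicate 2 and 0.0843 without control replicate 3), and 13 were higher with the block. Of the 13 mitochondrially encoded mRNAs 0 passed edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.383; 0.0231 without KO replicate 1). With the replicate block, 6 p53 targets rose and 4 fell, and 11 unfolded protein genes rose and 10 fell. With it, 4 motility genes rose and 14 fell, and 10 dissociation genes rose and 10 fell. With 1 library left out, between 0 and 2 unfolded protein genes rose and between 1 and 4 fell. Between 3 and 6 motility genes then fell, and at most 1 Notch gene rose and at most 1 fell. Of the dissociation genes, between 1 and 6 then rose and between 0 and 3 fell. Without KO replicate 3, 2 ribosomal protein and 3 respiratory chain genes rose.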

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

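The 2-level batch term, leaving out both replicate-3 libraries and the replicate block with an estimated correlation were chosen after the data had been seen. The count of 1427 genes stayed within 1.5 times of itself with DESeq2 (1439), limma-voom (1372), DESeq2 size factors (1444), library totals (1462), no filter (2026), the stricter filter (1388), robust estimation off (1396) and without the 20 most abundant genes (1410). It was 4983 with the replicate block, 5004 with the block without the 20 most abundant genes, 5102 with the 2-level batch term (2570 higher, 2532 lower), 3754 without both replicate-3 libraries, and 29 (6 higher, 23 lower) with glmTreat against a log2 fold change of 1. Leaving out 1 library gave 572 to 1741 genes. The lower share of calls was 66.2% in the group fit and 49.4% with the block; the block removes the difference of replicate 3 from the residual spread, which went from 10.5% to 4.13%. The stricter test by glmTreat asks for changes above 2-fold. For the left-out libraries the cause was not tested.

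Of the 33 lists, 15 were called by camera, 12 to 17 under the other scalings, filters, batch terms and left-out libraries, and 19 by fry. With an estimated correlation 2 lists were called. With the replicate block and an estimated correlation 0 were called, and 5 had an unadjusted p under 0.05. Few residual degrees of freedom remain in that setting, so it has little power. With the block, fry called 21. The block ended the calls of the Wnt and leukocyte lists and changed no other list call. Among 132 named genes, 125 were called. In those, 0 changed direction in any alternative; 42 lost their call in edgeR when 1 library was left out and 107 with glmTreat. NDC80 and DNAJB1 also lost theirs with no filter (adjusted p 0.0773 and 0.0533) and HES4 in DESeq2 (0.0629). FGFR3, FGFBP3 and PDGFRB passed with the block, which changed no other named call. ETV5, which was not called, had a log2 fold change of -0.0059 with the stricter filter and -0.018 without control replicate 2, and -0.018 to 0.043 over the left-out libraries. The cause of these differences was not tested. Under the other scalings and DESeq2 the median log2 fold change of all genes was at most 0.0119. Depth limits genes near the floor, such as CDH2 (mean 0.497 CPM; log2 fold change 1.90, SE 0.45).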

Other observations

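The tests of depth and of fragment size, read length or counting for replicate 3, and those on the interferon genes called higher, were chosen only after the result had been seen, as were the genes named in this paragraph and the next. Some lipid genes outside the cholesterol list were lower; they form no fixed list and were not tested as a set. The stearoyl-CoA desaturase SCD fell from 1528 ± 35.9 to 778 ± 19.3 CPM (log2 fold change -0.97, SE 0.06, edgeR adjusted p = 5.03e-05), FASN, fatty acid synthase, had a log2 fold change of -0.57 (SE 0.07) and the lipins LPIN1 and LPIN2 had -0.69 (SE 0.06) and -0.88 (SE 0.08). The sterol regulator SREBF2 was lower (-0.73, SE 0.07), SREBF1 was not past the threshold (-0.21, SE 0.07, edgeR adjusted p = 0.107; 2.54e-05 with the replicate block), and the cholesterol exporter ABCA1 was higher (0.56, SE 0.11).

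Within the hypoxia list the members did not move alike. VEGFA (0.02, SE 0.10, edgeR adjusted p = 0.926) and the glucose transporter SLC2A1 (-0.05, SE 0.07, edgeR adjusted p = 0.729), which are widely used hypoxia markers, did not pass. Beside them, CA9 was 12.1-fold lower, and BNIP3L (-1.06, SE 0.06) and PDK1 (-1.06, SE 0.08), nuclear genes for mitochondrial proteins, were lower. Transcripts of HIF1A (0.23, SE 0.06, edgeR adjusted p = 0.0572; 1.09e-07 with the replicate block), EPAS1 (0.24, SE 0.08, 0.117; 0.00291 with the block) and ARNT (-0.09, SE 0.08, 0.551) were not lower. Trefoil factors TFF1 (-1.12, SE 0.19), TFF2 (-1.49, SE 0.10) and TFF3 (-1.97, SE 0.25) and the mucin MUC1 (-1.26, SE 0.25) fell, while MUC5AC rose. CST2, a close copy of CST1, was 7.67-fold lower (0.44 ± 0.30 CPM in KO), so the decrease was seen in each of these 3 cystatins, though reads shared among them cannot be separated here.

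The lower hypoxia genes were set against 3 explanations. The bootstrap intervals given here and for the interferon genes resampled the genes of a list, as if independent. They do not measure the spread between cultures. If cultures of a single replicate number had caused the pattern, a pair would have lacked it. The weakest of the 3 same-numbered medians was -0.67 (95% bootstrap interval -1.13 to -0.49), and 26 to 28 of 30 members were lower in each pair. Removal of a trend on GC content and transcript length left a median of -0.64, against -0.63 before. The fitted trend was small (SD 0.038 over 14361 genes), so its removal could hardly change that median. Slower growth, and so less oxygen use in the KO gels, was predicted to lower proliferation genes. The lower of their 2 list medians was 0.15 (mitosis, 95% interval 0.11 to 0.20), so slower cycling was not seen in these transcripts. Counts scaled to library size do not give the number of cells in a gel or its oxygen use. The test therefore cannot decide on cell density. The tables argue against a single replicate number, and against a GC and length trend of the size fitted here, as the whole source. Lower cell density in the KO gels stays open. An effect of the knockout, and gel position, seeding density and clone, which the labels do not give, were not tested and stay open.

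The interferon genes were weighed in the same way. The weakest same-numbered median was 0.11 (95% bootstrap interval -0.01 to 0.31), and the median after removal of the GC and length trend was 0.13 (-0.01 to 0.48). As the members go both ways, neither value decides for the list as a whole, where a single pair or a GC and length bias cannot be told apart from an effect of the knockout. For the members called higher the tables argue against a single pair, and against a GC and length trend of the size fitted here. Members called in 2 pairs, 5, 4 and 14 with pair 1, 2 or 3 left out, were all higher in the left-out pair, with a lowest median of 0.712 (0.563 to 0.945). The 14 called members had a median of 0.711 (0.574 to 0.981) after removal of the trend, against 0.716 before. The fitted trend was small (SD 0.038 over 14361 genes, from -0.0063 to 0.031 in these members). Its removal could therefore hardly change that median, and the members had been chosen as higher in these same libraries. An effect of the knockout, and clone, were not tested for them and stay open.

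Replicate 3 of both groups stood apart from replicates 1 and 2. A difference in depth has the tables against it, since the replicate-3 total was the highest of the control group and the lowest of the KO group (KO over control 0.777). The mitochondrial share of control replicate 3 lay inside the range of replicates 1 and 2 (0 percentage points outside it), whose upper end was control replicate 2 (4.26%). This argues against a shift of that share beyond the spread of replicates 1 and 2. The mitochondrially encoded mRNAs were still lower in replicate 3 than in the mean of replicates 1 and 2. Their median log2 difference was -0.31 in control and -0.22 in KO, so a smaller shift of these transcripts stays open. Of 64 genes shifted at least 2-fold in both groups, 27 were higher and 37 lower in replicate 3. Of the 64, 53.1% were pseudogenes or had no transcript of 1000 nt, against 3.19% of 10676 other genes (Fisher's exact test, two-sided, p = 4.12e-33, with genes not being independent). That share goes with a difference in fragment size, read length or read counting in replicate 3, which the values do not tell apart. No biological explanation was tested for the shift of replicate 3, and the labels give no batch.

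A hypothesis was that aryl hydrocarbon receptor output was raised, since CYP1A1 (0.97, SE 0.12) and CYP1B1 (1.85, SE 0.10) rose. Of 9 other target genes listed, AHRR, UGT1A6 and CYP1A2 were not among the tested genes. Of the 6 measured, 5 rose (TIPARP, NQO1, SERPINB2, SLC7A5 and EREG) and ALDH3A1 fell (-0.65, SE 0.12), with a median of 0.35. The values are consistent with the hypothesis; several of these genes may also answer to other signals, SLC7A5 and EREG lost their calls without some single libraries (edgeR adjusted p of up to 0.0766 and 0.0769), and the transcript of the receptor itself, AHR, had a log2 fold change of 0.11 (SE 0.07, edgeR adjusted p = 0.351).

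Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 1427 genes and the highest other gave 0 by edgeR and by limma-voom (up to 1362 genes at an unadjusted p under 0.05, for a split with replicate 3 of both groups on the same side); 1 of 10 splits gave as many genes. For lists, the real split gave 15 and the highest other 9, with 4 to 9 lists called in every other split, and 1 of 10 gave as many. Among the splits that part all 3 pairs, the other 3 gave 0 genes with the replicate block, against 4983 for the real split. In every other split each side mixes the groups, so the group difference adds to the residual spread. Few genes would then pass whatever caused that difference. The camera test with a preset correlation called lists in these splits. As they mix the groups unevenly, part of the group difference remains in them, and the lists called there need not all be false.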
